A study of Mus musculus with 6 samples.

How the data were processed

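The series measured RNA in biliary epithelial cells, the epithelial cells that line the bile ducts, from the livers of wild-type female C57BL/6 mice. There were 3 samples from non-pregnant mice and 3 from pregnant mice at dpc8, that is 8 days post coitum. Per the labels' protocols, livers were perfused and digested with enzymes, hepatocytes were removed by slow centrifugation, and the biliary cells were sorted by flow cytometry from the remaining non-parenchymal fraction. The antibodies that defined the sorting gate are not given in the sources used here. Total RNA was depleted of ribosomal RNA and made into sequencing libraries with the KAPA RNA HyperPrep kit with RiboErase, per the labels' protocols. Nothing in the labels says in words that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

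The authors deposited FPKM values (fragments per kilobase of exon, scaled to the sequencing depth of the library), one column per sample, for 21700 genes. The submitters' processing notes name cutadapt 3.4, STAR 2.7.9a, HTSeq 0.13.5 and DESeq2 1.30.1 and the mouse build mm10, without saying what each was used for. Of the 21700 genes, 21640 are protein-coding in GENCODE vM21, which annotates the same build, and 28 had no length there. The value of each gene times its GENCODE union exon length was, for 98.5% of the values above 0, a whole multiple of 1 step per sample within a tolerance of 0.01. Divided by the step, each such product gave a recovered number of fragments. Summed over genes, these were 28916147, 30188469 and 35083751 in the non-pregnant libraries 1 to 3. In the pregnant libraries 1 to 3 they were 26721075, 30662595 and 25047887. Between 15928 and 16245 genes were above 0 in a library, and 4296 were at 0 in all 6. Fragment numbers quoted for single genes are these recovered values, and 95% intervals made from them (exact Clopper-Pearson) cover counting error only, since the fragments carried no molecular identifiers. Because FPKM divides by the fragments of all genes, a change in a few abundant genes moves all other values slightly. The median log2 change over all tested genes was -0.02 as deposited and between -0.03 and 0.00 under the other scalings.

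Groups and replicate numbers were taken from the sample titles, which number the libraries 1 to 3 in each group. The sample descriptions number non-pregnant library 3, which stood apart in several measures, as 4. The only comparison the labels give is pregnant against non-pregnant, and changes are coded pregnant minus non-pregnant. FPKM is not a count, so values were tested as log2(FPKM + 1), with a pseudocount of 1 FPKM, which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 6 libraries (11412) were tested two-sided with limma 3.58.1 (trended empirical Bayes) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1. Gene lists for pathways and for the cell types that a sort of liver cells could hold (32 lists) were fixed before the data were examined, as were the rule for named genes, the tests and most alternatives. The 26 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The other 6 lists are given as values. Camera with an estimated correlation and limma's fry were alternatives.

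The text names the genes past the threshold whose groups did not overlap (at most 12 per direction, largest changes first, leaving out gene models without a name, and filled up to 6 with the smallest p where fewer passed), up to 4 members of each list by smallest p, and always Krt19, Krt7, Epcam, Sox9, Spp1, Alb and Mki67. Genes named outside that rule are said to have been chosen after their values were seen.

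The fit was tested on simulated data for the 11368 tested genes whose fragments were recovered, drawn from the real means and library sizes. It recovered 99% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, and 3.1% of its calls were unchanged genes. Of 26 unchanged lists, camera at the preset correlation called 1, fry called 2 and camera with an estimated correlation called 0, and each called a list of genes raised 1.5-fold. The spread simulated was the same for all libraries, so the simulation does not cover libraries that stand apart. Each gene was given the median spread of genes at its level, and genes were drawn independently of each other. The simulation therefore does not cover genes of larger spread or genes that vary together. Its shares do not show how often the fit or the list tests are right in the real data.

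The alternatives tried were other pseudocounts, other filters on low values, 3 other scalings, a replicate block, other empirical Bayes settings, array weights, leaving out each library in turn and an adjusted threshold of 0.1. After the data were seen, limma-voom on the recovered fragments, a fit with the endothelial marker level as a covariate and a fit after removing a trend with GC content within each library (loess, span 0.5) were added. Differences in splicing were not analysed here. Some genes that the rule for named genes would name are not reported here by name.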

Results

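The data were 6 RNA-seq libraries of sorted biliary epithelial cells, 3 from non-pregnant mice and 3 from pregnant mice at 8 days post coitum. Each library held between 25047887 and 35083751 recovered fragments. The comparison asks how the transcriptome of these cells in early pregnancy differs from that outside pregnancy.

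All 6 libraries had the profile of biliary epithelium. Spp1, the secreted phosphoprotein osteopontin, stood at 4567 ± 632 FPKM (SD, n = 3) in non-pregnant and 5711 ± 209 FPKM (SD, n = 3) in pregnant libraries. The biliary transcription factor Sox9 stood at 287 ± 17.0 and 302 ± 26.5 FPKM, the adhesion molecule Epcam at 183 ± 1.16 and 192 ± 2.54 FPKM, and the keratins Krt19 at 281 ± 58.6 and 369 ± 22.6 FPKM and Krt7 at 25.01 ± 5.46 and 26.9 ± 4.21 FPKM. None of these 5 genes passed the test (limma adjusted p from 0.351 for Krt19 to 0.763 for Krt7). The biliary identity list as a whole was shifted up by a median of 0.28 on the log2 scale, with 20 of 21 members above 0 (camera adjusted p = 1.59e-06; adjusted p = 0.407 with an estimated correlation). No member passed over all genes tested, and 0 passed adjusted over the list alone. Ehf, Muc1, Cd24a and Cldn7 had the smallest p of the list, with Muc1 at 106 ± 24.0 and 154 ± 17.1 FPKM. Without non-pregnant library 3 the list's median was 0.12.

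The pregnant libraries resembled each other more than the non-pregnant ones did. Spearman correlations over the tested genes lay between 0.991 and 0.995 among the pregnant libraries, between 0.956 and 0.979 among the non-pregnant ones and between 0.958 and 0.987 across groups. The first principal component (50.3% of the variance) set non-pregnant library 3 apart and the second (28.3%) non-pregnant library 2.

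In pregnancy, 5 genes known from liver macrophages rose more than 10-fold from a low level, A1bg rose from a few fragments per library, and 3 genes for secreted or lipid droplet proteins best known from hepatocytes fell. In all, 10 of 11412 genes changed, 7 upward and 3 downward (limma adjusted p from 0.0357 to 0.0393), and each was higher, or lower, in all 3 pregnant libraries than in all 3 non-pregnant ones. At an unadjusted p under 0.05 there were 1528 genes, 809 higher and 719 lower. The groups did not overlap for 22.1% of the genes, 1130 higher and 1395 lower in pregnancy, where chance gives 10%.

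Of the 7 genes that rose, 5 are known from macrophages. Cd5l, a secreted macrophage protein, went from 0.918 ± 0.521 to 14.7 ± 5.40 FPKM (SD, n = 3 each), a 16.0-fold difference (log2 change 3.01 ± 0.285, SE; limma adjusted p = 0.0357). The complement genes C1qa and C1qc rose 14.3-fold and 15.8-fold, Ctss, which encodes the lysosomal protease cathepsin S, rose 14.9-fold, and Fcna, the plasma lectin ficolin A, rose 10.8-fold. With robust empirical Bayes none of these 5 was called (limma adjusted p from 0.0674 for Cd5l to 0.0866 for C1qa and Fcna), while the other 5 of the 10 genes were. Their summed fragments were between 63 and 170 over the non-pregnant and between 849 and 2494 over the pregnant libraries. In pregnant libraries 1, 2 and 3 Cd5l stood at 20.1, 14.7 and 9.29 FPKM and C1qa at 16.2, 12.04 and 6.23 FPKM. In mm10 coordinates Cd5l (ENSMUSG00000015854) spans chromosome 3 from 87357881 to 87371073, Ctss (ENSMUSG00000038642) chromosome 3 from 95526786 to 95556403, and Fcna (ENSMUSG00000026938) chromosome 2 from 25624666 to 25628030. C1qc (ENSMUSG00000036896; 136889804 to 136893065) and C1qa (ENSMUSG00000036887; 136895917 to 136898803) are neighbours on chromosome 4.

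The other genes that rose were A1bg, which encodes the plasma protein alpha-1-B glycoprotein, and Atp8b3, which encodes a phospholipid-transporting ATPase. A1bg (ENSMUSG00000022347; chromosome 15, 60896859 to 60923012) had 1, 3 and 1 fragments in the non-pregnant and 269, 386 and 140 in the pregnant libraries, a pooled ratio of 181 with a 95% counting interval from 77.1 to 558. Its values in pregnancy were 4.21, 5.21 and 2.31 FPKM (log2 change 2.21 ± 0.215, SE; limma adjusted p = 0.0357). Atp8b3 (ENSMUSG00000003341; chromosome 10, 80519584 to 80539124) was at 0.569 ± 0.00870 FPKM in non-pregnant and 1.79 ± 0.0436 FPKM in pregnant libraries (SD, n = 3 each), 3.15-fold higher. It had 78, 81 and 93 fragments in the non-pregnant and 229, 264 and 208 in the pregnant libraries. The pooled ratio was 3.16 with a 95% counting interval from 2.73 to 3.66. At such fragment numbers counting error alone is larger than these SDs, which therefore overstate the precision.

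The genes that fell were Ahsg, Fetub and Hsd17b13. Ahsg encodes fetuin-A, an abundant plasma protein, and went from 516, 502 and 664 FPKM to 195, 221 and 143 FPKM, a ratio of 0.332 (log2 change -1.60 ± 0.183, SE; limma adjusted p = 0.0368). Fetub, which encodes the related fetuin-B, went from 14.6 ± 1.08 to 7.78 ± 0.610 FPKM (SD, n = 3 each), a ratio of 0.533. Hsd17b13, which encodes a lipid droplet enzyme, went from 3.58 ± 0.390 to 1.46 ± 0.0761 FPKM, a ratio of 0.408. Ahsg (ENSMUSG00000022868; 22891277 to 22899449) and Fetub (ENSMUSG00000022871; 22918334 to 22939778) lie beside each other on chromosome 16, and Hsd17b13 (ENSMUSG00000034528; 103955440 to 103977410) lies on chromosome 5. Meltf, Inhbb and Gpx3 came next among the lower genes and did not pass (limma adjusted p of 0.0565, 0.0809 and 0.0854), with Inhbb, a subunit of activins and inhibins, at 10.9 ± 1.26 and 6.06 ± 0.523 FPKM. With limma no gene was called without non-pregnant library 1, without non-pregnant library 3, without pregnant library 1 or without pregnant library 2 (1321, 1419, 857 and 1061 genes at an unadjusted p under 0.05), without non-pregnant library 2 there were 91 higher and 42 lower, all 10 among them, and without pregnant library 3 there were 12 higher and 0 lower, with Ahsg, Fetub, Hsd17b13 and Atp8b3 no longer called. The same 4 were not called with the replicate block (13 higher and 0 lower), none of the 10 was with no filter on low values and Atp8b3 was not with quantile normalisation, while limma-voom on the recovered fragments called Atp8b3 alone and the directions of all 10 held in each of these fits.

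**Figure D1:**
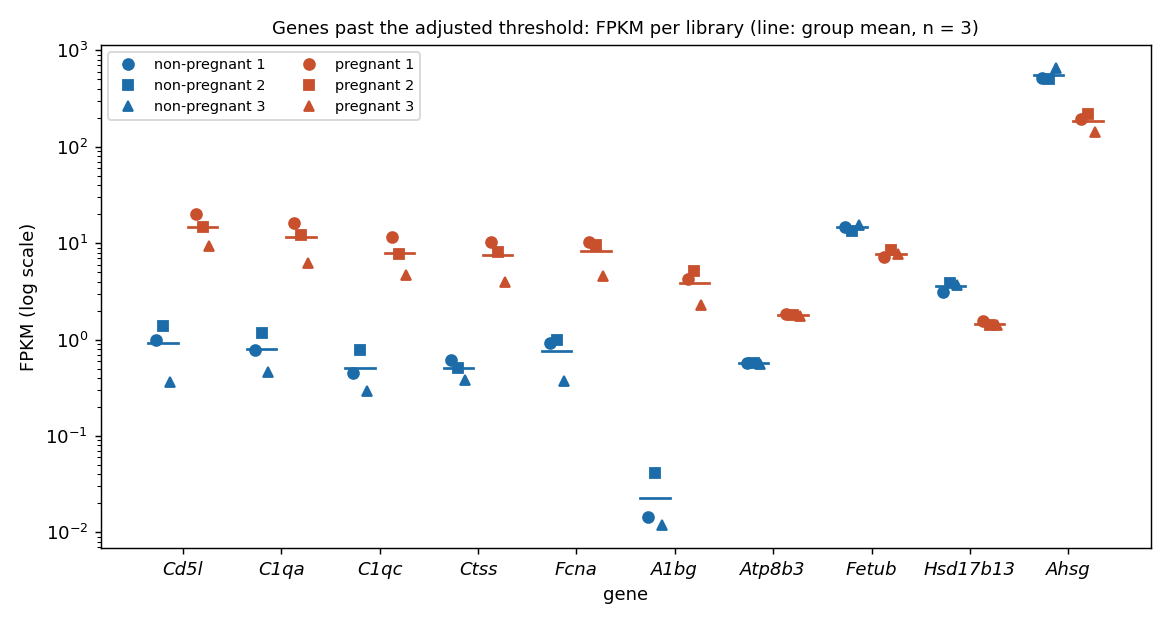
FPKM of the 10 genes past the adjusted threshold in each library, on a log axis, with the non-pregnant libraries in blue, the pregnant ones in orange and lines at the group means (n = 3). The groups do not overlap for any of the 10, and Ahsg spans 502 to 664 FPKM in non-pregnant and 143 to 221 FPKM in pregnant libraries.

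Transcripts of Kupffer cells, the resident macrophages of the liver, formed the list with the largest shift, a median of 2.17 on the log2 scale (camera adjusted p = 1.45e-14; adjusted p = 0.407 with an estimated correlation). All 12 tested members lay above 0, 3 rose over all genes tested (Cd5l, C1qa and C1qc) and 10 rose adjusted over the list alone. Over all genes tested, 8 rose without non-pregnant library 2 and 0 without non-pregnant library 3. Clec4f, a Kupffer cell lectin, stood at 1.07, 1.51 and 0.299 FPKM in non-pregnant and 18.0, 14.2 and 5.90 FPKM in pregnant libraries (limma adjusted p = 0.0854). The members that did not pass, Cd68 and Csf1r, were chosen for mention after their values were seen, and stood at 36.0 to 40.5 FPKM and 19.1 to 43.7 FPKM over all 6 libraries. The median FPKM of the list was 0.810, 1.38 and 0.278 in non-pregnant libraries 1 to 3 and 14.3, 9.59 and 4.99 in pregnant libraries 1 to 3. In pregnant library 3 the members stood at a median of 0.364 of their level in pregnant library 1.

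Antigen presentation and interferon genes were also shifted up in pregnancy. All 6 tested MHC class II genes lay above 0, with a median log2 change of 0.71, and all 6 rose adjusted over the list alone, while 0 passed over all genes tested (camera adjusted p = 3.23e-06; adjusted p = 0.407 with an estimated correlation). H2-Ab1 was at 4.54 ± 0.883 and 7.97 ± 1.55 FPKM (SD, n = 3 each), H2-Aa at 0.996 ± 0.372 and 2.55 ± 1.06 FPKM and the invariant chain gene Cd74 at 25.4 ± 7.12 and 43.8 ± 12.1 FPKM. These libraries differed in macrophage transcripts as given above. Of the 12 tested macrophage markers 11 stood in the order pregnant library 1 over 2 over 3, against 20.4% of all tested genes. That order was found in 4 of the 6 MHC class II genes, and 0 of the 6 were highest in pregnant library 3. Among the type I interferon-stimulated genes all 18 tested members lay above 0, with a median of 0.44, and 10 rose adjusted over the list alone while 0 passed over all genes tested (camera adjusted p = 8.61e-12; adjusted p = 0.407 with an estimated correlation). Oas1a, an antiviral sensor of double-stranded RNA, was 2.15-fold higher, Oasl2 1.52-fold and Rtp4 1.51-fold higher in the pregnant group means, and none of the 3 passed over all genes tested. The order of the macrophage markers was found in 5 of the 18 interferon genes, and 8 of the 18 were highest in pregnant library 3. Without non-pregnant library 3 the interferon median was 0.27, with 0 members past the threshold over all genes tested. Without non-pregnant library 2 it was 0.54, with 4 members past it.

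Inflammatory genes of the NF-kB and acute-phase list had a median log2 change of 0.34, with 12 of 14 members above 0 (camera adjusted p = 1.05e-05; adjusted p = 0.407 with an estimated correlation). Adjusted over the list alone 7 members rose and 1 fell, and 0 passed over all genes tested. Macrophage markers differed between the same groups of libraries by a median of 2.17 on the log2 scale. Their order of pregnant library 1 over 2 over 3 was found in 2 of the 14 members, against 20.4% of all tested genes. Of the 14 members 7 were highest in pregnant library 3, as were 16.9% of all tested genes. Tnfaip3, a feedback inhibitor of NF-kB, stood at 11.0 ± 2.96 and 19.2 ± 1.12 FPKM (SD, n = 3 each), the acute-phase gene Orm1 at 0.888 ± 0.372 and 1.93 ± 0.245 FPKM, and the chemokine gene Cxcl1 at 4.18 ± 0.875 and 7.78 ± 2.11 FPKM. The member that fell adjusted over the list alone was the adhesion molecule Icam1, at 39.0 ± 4.88 and 31.6 ± 1.75 FPKM, chosen for mention after its values were seen.

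Genes of cell proliferation were shifted up as groups from a low level, and no single member passed over all genes tested. Macrophage markers differed between the same groups of libraries by a median of 2.17 on the log2 scale. Their order of pregnant library 1 over 2 over 3 was found in 4 of the 9 tested G2 and M phase genes and in 2 of the 22 tested S phase genes, against 20.4% of all tested genes. Of the S phase genes 20 were highest in pregnant library 3, as were 16.9% of all tested genes. The 4 G2 and M phase genes were Ube2c, Kif20a, Nusap1 and Ccnb2, chosen for mention after their values were seen. All 22 S phase genes lay above 0, with a median of 0.22 on the log2 scale and 0 past the threshold adjusted over the list alone (camera adjusted p = 1.59e-06; adjusted p = 0.407 with an estimated correlation). The replication helicase gene Mcm5 stood at 1.42, 2.38 and 1.98 FPKM in non-pregnant and 4.26, 3.19 and 8.96 FPKM in pregnant libraries, and Uhrf1, which maintains DNA methylation, at 2.48, 3.37 and 1.79 against 5.01, 4.09 and 8.83 FPKM. The S phase median was 0.12 without pregnant library 3 and 0.33 without pregnant library 2. Of the G2 and M phase genes 8 of 9 lay above 0, with a median of 0.32, and 3 rose adjusted over the list alone, Mki67, Top2a and Kif23 (camera adjusted p = 2.78e-05; adjusted p = 0.407 with an estimated correlation). Mki67, the proliferation marker, was at 1.24 ± 0.344 and 2.94 ± 0.705 FPKM (SD, n = 3 each), 2.38-fold higher in pregnancy (log2 change 0.81 ± 0.167, SE; limma adjusted p = 0.229). Replication-dependent histones did not shift as a list (camera adjusted p = 0.141), and 2 of 13 rose adjusted over the list alone, Hist1h1b and Hist1h3b. Without pregnant library 3 the histone list passed (camera adjusted p = 0.0384).

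Cholesterol biosynthesis genes had a median log2 change of 0.75, with 22 of 23 members above 0 (camera adjusted p = 1.7e-09; adjusted p = 0.407 with an estimated correlation). None of the 23 passed over all genes tested, and 0 passed adjusted over the list alone. Hmgcs1, which makes HMG-CoA, stood at 46.2, 79.1 and 25.6 FPKM in non-pregnant and 89.4, 85.3 and 88.1 FPKM in pregnant libraries, and Cyp51, the lanosterol demethylase, at 17.3, 31.4 and 6.80 against 36.2, 33.3 and 38.5 FPKM. Of the 23 genes 22 were lowest in non-pregnant library 3, as were 28.5% of all tested genes. Without that library the list's median was 0.41, and without non-pregnant library 2 it was 1.14, with 12 members past the threshold over all genes tested. Mitochondrially encoded genes had a median of 0.36, with all 7 above 0 and 1, mt-Nd2, past the threshold adjusted over the list alone (camera adjusted p = 0.000216; adjusted p = 0.407 with an estimated correlation), and mt-Nd2 stood at 176 ± 14.7 and 302 ± 95.5 FPKM (SD, n = 3 each). The list's median was 0.19 without pregnant library 3. Nuclear-encoded oxidative phosphorylation genes, cytosolic ribosomal proteins and the unfolded protein response did not pass as lists (camera adjusted p of 0.589, 0.0794 and 0.16) and held no member past the threshold adjusted over the list alone. Ribosomal proteins passed, lower in pregnancy, without non-pregnant library 1 or 2 or pregnant library 1 or 2 (camera adjusted p of 0.0194, 0.0216, 0.0165 and 0.0447), and not without non-pregnant library 3 or pregnant library 3 (0.625 and 0.52).

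Hormone and cytokine lists showed few shifts. Receptors for pregnancy hormones and growth factors had a median of -0.13 with 10 of 14 members below 0 (camera adjusted p = 0.0532), and Thrb, a thyroid hormone receptor, stood at 3.72 ± 1.25 and 2.25 ± 0.134 FPKM (SD, n = 3 each). The receptor list passed, lower in pregnancy, without non-pregnant library 2 or 3 or pregnant library 2 (camera adjusted p of 0.011, 0.0194 and 0.0299), and without non-pregnant library 1 its median was -0.07 (camera adjusted p = 0.287). Oestrogen-responsive genes did not pass as a list (camera adjusted p = 0.458), with Ccnd1, which encodes cyclin D1, at 76.7, 130 and 33.0 FPKM in non-pregnant and 153, 151 and 234 FPKM in pregnant libraries (limma adjusted p = 0.308). The STAT5 and cytokine feedback list did not pass either (camera adjusted p = 0.141), and adjusted over the list alone 3 of its 13 members rose, Igf1, Oas1a and Socs2, and 1 fell, Socs3. Igf1, the growth factor of the growth hormone axis, was at 7.74 ± 0.646 and 11.3 ± 0.782 FPKM (log2 change 0.50 ± 0.086, SE; limma adjusted p = 0.171). Of the ligands of the EGF family 3 genes were tested, Btc, Tgfa and Hbegf, too few for a list test, and Hbegf stood at 89.7 ± 17.0 and 88.0 ± 7.76 FPKM.

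Lists of ductal signalling gave small shifts. Targets of YAP and TEAD had a median of 0.01, with 10 of 20 members above 0, and a camera adjusted p of 0.0314 upward (adjusted p = 0.407 with an estimated correlation). The 3 members that rose adjusted over the list alone were F3, Axl and Tgfb2. F3, or tissue factor, was at 27.0 ± 1.18 and 41.4 ± 4.43 FPKM (SD, n = 3 each; limma adjusted p = 0.124), and Axl, a receptor tyrosine kinase that macrophages also express, was at 0.659, 0.775 and 0.468 FPKM in non-pregnant and 3.43, 2.42 and 1.78 FPKM in pregnant libraries. The ductular reaction list had a median of 0.17 (camera adjusted p = 0.0356; adjusted p = 0.407 with an estimated correlation) with 2 members, Edn1 and Tgfb2, up adjusted over the list alone, while Mmp7, a matrix protease, stood at 41.2, 19.5 and 45.6 against 15.8, 21.0 and 10.8 FPKM (limma adjusted p = 0.301). The YAP and ductular lists no longer passed without non-pregnant library 3 (camera adjusted p of 0.155 and 0.207) or without pregnant library 1 (0.0525 for each), with YAP and ductular medians of -0.02 and 0.06 without non-pregnant library 3. The YAP median was 0.06 without non-pregnant library 1 or 2, -0.004 without pregnant library 1 and 0.04 without pregnant library 3, and the ductular median was 0.11 without non-pregnant library 2 or pregnant library 3. Immediate-early genes had a median of 0.07, with 13 of 23 members above 0 (camera adjusted p = 0.0356; adjusted p = 0.587 with an estimated correlation), with 1, Ier3, up adjusted over the list alone, and did not pass without non-pregnant library 2 or pregnant library 1 or 3 (camera adjusted p of 0.729, 0.0598 and 0.357; medians of -0.02, 0.10 and -0.02). Without non-pregnant library 3 or pregnant library 2 the median was 0.11 or 0.13.

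Bile secretion genes did not shift as a list, whose mean of -0.05 and median of -0.01 lay below 0 while camera's test pointed up (camera adjusted p = 0.768). Adjusted over the list alone, 2 of its 14 members rose, Car2 and Cftr, and 1 fell, Sstr2. Cftr, the chloride channel of bile duct cells, was at 5.37 ± 1.301 and 8.94 ± 0.958 FPKM (SD, n = 3 each; limma adjusted p = 0.279), and Car2, a carbonic anhydrase, was at 20.7 ± 1.82 and 27.2 ± 1.92 FPKM. The Notch and Wnt lists did not pass (camera adjusted p of 0.216 and 0.352), nor did the p53 list (0.523), in which Bbc3 and Gdf15 rose and Fas fell adjusted over the list alone.

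**Figure D2:**
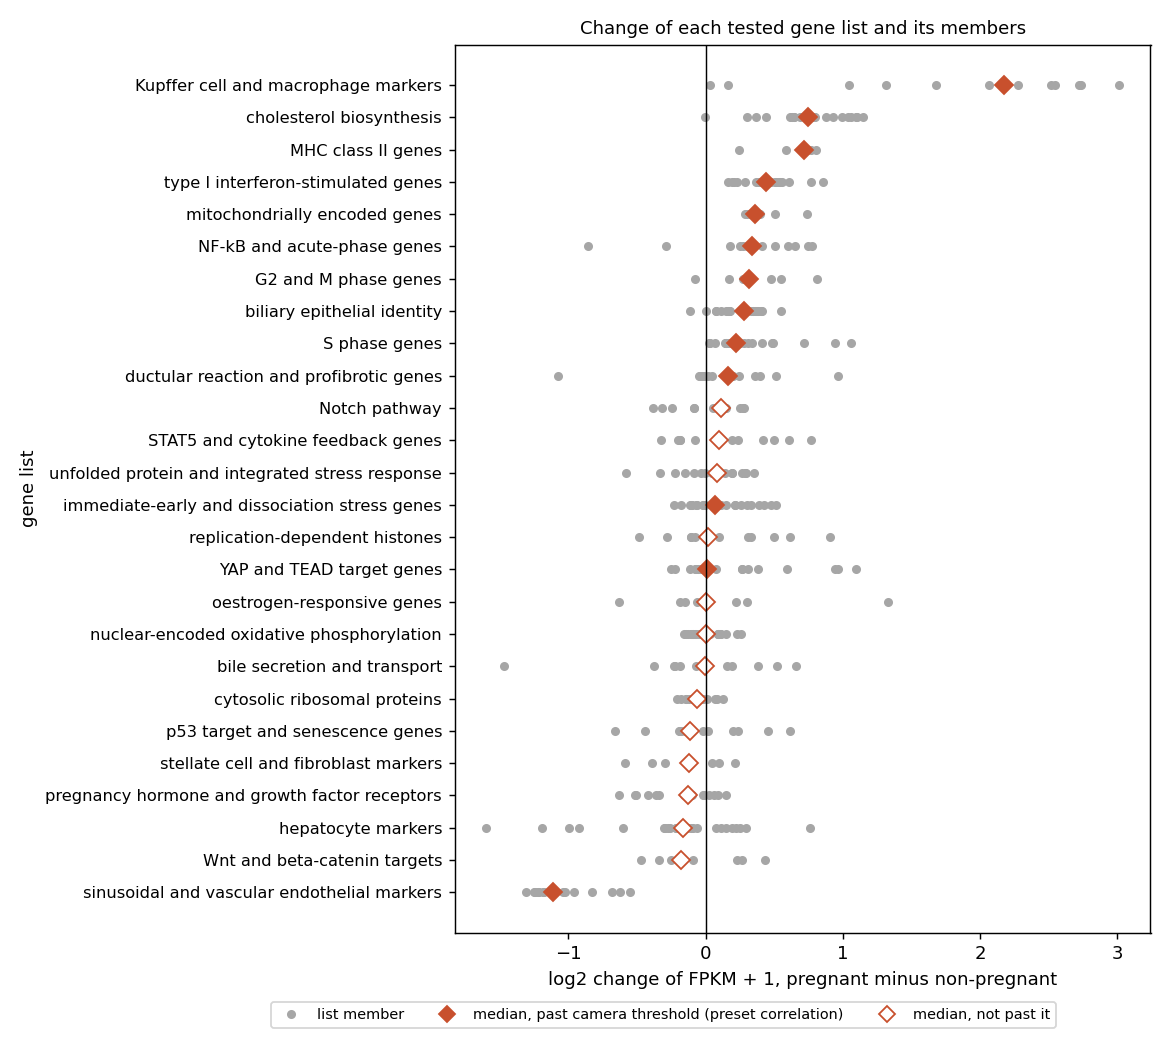
Log2 change of FPKM + 1, pregnant minus non-pregnant, for the members (grey points) and the median (diamonds) of the 26 tested gene lists, filled where camera at the preset correlation passed the threshold. The macrophage list has the highest median, 2.17, and the endothelial list the lowest, -1.11.

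Markers of other liver cell types differed between libraries. Sinusoidal and vascular endothelial genes had a median log2 change of -1.11, with all 16 tested members below 0 and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.000558; adjusted p = 0.519 with an estimated correlation). All 16 were highest in non-pregnant library 2, where the list's median was 22.3 FPKM against 1.95 to 4.07 FPKM in the other libraries, and without that library the median log2 change was -0.15 (camera adjusted p = 0.298). Without non-pregnant library 3 it was -1.72. Lyve1, a marker of sinusoidal endothelium, stood at 3.94, 13.8 and 1.03 FPKM in non-pregnant and 1.12, 2.24 and 0.731 FPKM in pregnant libraries.

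Hepatocyte markers had a median of -0.17 (camera adjusted p = 0.0532), and 4 of 25 fell adjusted over the list alone, Ahsg, Apoh, Fgg and G6pc. Apoh, or beta-2-glycoprotein I, was at 21.2 ± 6.10 and 8.65 ± 2.16 FPKM (SD, n = 3 each; limma adjusted p = 0.205). Alb, which encodes albumin, stood at 2327 ± 310 and 2147 ± 110 FPKM (limma adjusted p = 0.754). Without non-pregnant library 2 the list's median was 0.03 (camera adjusted p = 0.896), with 3 members lower and 1 higher past the threshold over all genes tested. The list passed, lower in pregnancy, without non-pregnant library 1 or 3 or pregnant library 1 or 2 (camera adjusted p of 0.00973, 0.00432, 0.0109 and 0.00278). Its median was -0.25 without pregnant library 2. Without pregnant library 3 its median was -0.06 (camera adjusted p = 0.429). Stellate cell and fibroblast markers did not pass (camera adjusted p = 0.352), with the matrix gene Dcn at 1.80 ± 0.606 and 0.847 ± 0.277 FPKM.

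Lymphocyte, granulocyte and red cell markers were near the lower end of the range. Of the T and NK cell markers 1 gene, Lck, was tested, at 1.51 ± 0.401 and 1.84 ± 0.133 FPKM (SD, n = 3 each), and of the B cell markers 2 were, Cd79a at 1.71 ± 0.299 and 2.38 ± 0.194 FPKM and Mzb1 at 0.966 ± 0.114 and 1.05 ± 0.284 FPKM. No neutrophil or erythroid marker reached the mean of 1 FPKM. Of the mesothelial markers 4 were tested, with Gpm6a at 15.5 ± 0.887 and 17.0 ± 2.13 FPKM, and none passed.

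**Figure D3:**
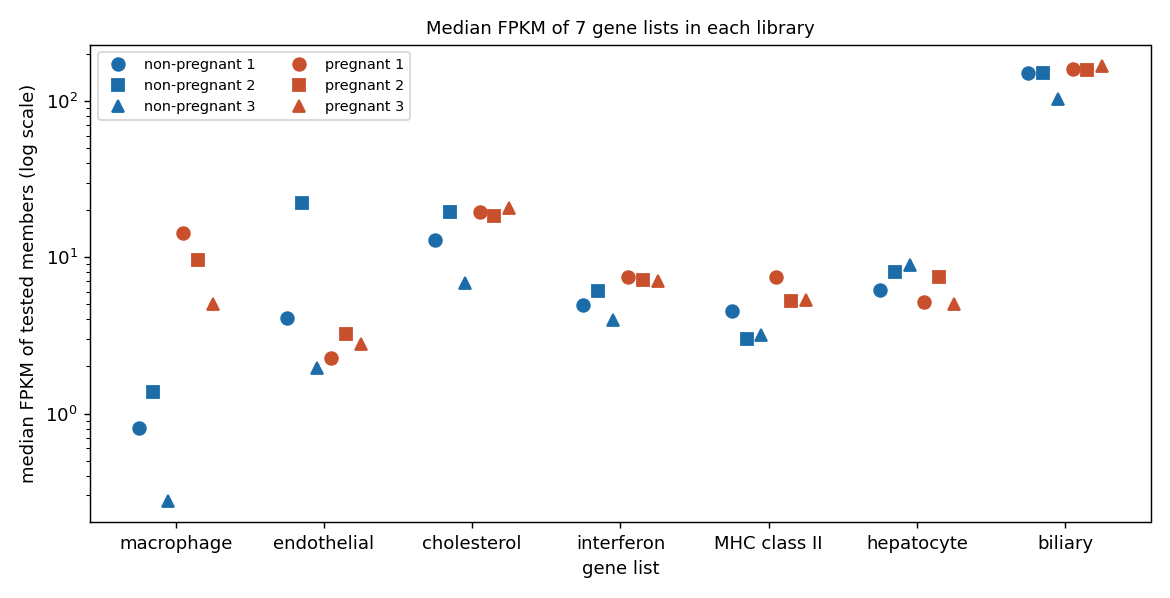
Median FPKM, on a log axis, of the tested members of 7 gene lists in each library, non-pregnant in blue and pregnant in orange. Macrophage markers lie between 0.278 and 1.38 FPKM in non-pregnant and between 4.99 and 14.3 FPKM in pregnant libraries, endothelial markers stand apart in non-pregnant library 2 at 22.3 FPKM, and cholesterol genes are lowest in non-pregnant library 3 at 6.80 FPKM.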

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

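The limma-voom, endothelial covariate and GC fits were chosen after the data were seen. The number of changed genes depended on the setting, while all 10 called genes kept their direction wherever they were tested. The 7 higher and 3 lower genes became 0 and 0 with no filter on low values (limma; 2258 at an unadjusted p under 0.05), where 17404 genes were tested, 2 and 2 with a filter of 5 FPKM, under which 4 of the 10 were tested and all 4 kept, 2 and 3 with robust empirical Bayes, under which none of the 5 macrophage genes was called, 720 and 581 with array weights, 13 and 6 at an adjusted p under 0.1, 1 and 0 with limma-voom (1497 at an unadjusted p under 0.05) and 506 and 363 with the endothelial covariate. Leaving out 1 library gave between 0 and 91 higher and between 0 and 42 lower, both highest without non-pregnant library 2. The replicate block gave 13 and 0, and both it and the fit without pregnant library 3 (12 and 0) kept 6 of the 10. The deviations of libraries with the same number correlated at 0.07, 0.02 and -0.14 and 0 of 6 libraries correlated best with its own number, so the numbers were not taken to pair the samples. By the numbers of the sample descriptions, non-pregnant library 3 is number 4 and has no partner in pregnancy, so the block and the last correlation rest on the title numbers. The cause of these moves was not tested. Of the 10 splits of the 6 libraries, too few for a share under 0.05, 1 gave as many genes, the real one (10, highest other 0), and 2 gave as many lists (13, highest other 17).

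The lists called up and down, 12 and 1 as reported, became 0 and 0 with an estimated correlation and 0 and 0 with fry. The number up lay within 1.5 times of 12 elsewhere. The number down was 2 with a pseudocount of 0.1, the filter of 5 FPKM, array weights, limma-voom and the endothelial covariate, 3 with median-of-ratios scaling and the block, 4 with no filter, the filter of 0.1 FPKM and quantile scaling, and between 1 and 4 without single libraries.

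Some values turned in direction, the cause not tested. Past the threshold as reported, camera's direction turned with the endothelial covariate for immediate-early genes (median -0.052) and endothelial markers (0.041, the markers that made the covariate), both then not past it. Among lists not past it as reported, camera's direction turned for bile secretion with no filter (median -0.013), the filter of 0.1 FPKM (-0.005), array weights (-0.148) and without non-pregnant library 3 (-0.117, the lowest of a range up to 0.052 without single libraries). It turned for histones with the filter of 5 FPKM (-0.091), ribosomal proteins with array weights (-0.002) and without non-pregnant library 3 (-0.001, range from -0.109), oxidative phosphorylation without non-pregnant library 1 (-0.054, range up to 0.033) and stellate markers with the covariate (-0.072) and without non-pregnant library 2 (-0.069, range -0.187 to -0.058). The log2 change of genes that did not pass turned for Krt7 with array weights (-0.107) and without non-pregnant library 3 (-0.072, range up to 0.215), Alb with array weights (0.084), Tgfa without non-pregnant library 3 (0.064) and Mzb1 with quantile scaling (-0.017), array weights (-0.01) and without pregnant library 2 (-0.057, range up to 0.136). With quantile scaling Spp1 stood at -0.0, which is no change rather than a turn. For A1bg, with 5 fragments over the non-pregnant libraries, depth limits the size of the ratio.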

Other observations

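All tests in this part, and the genes it adds, were chosen after the values were seen. Non-pregnant library 3 and pregnant library 3 had profiles of their own for PPAR-alpha targets and the clock. In non-pregnant library 3 all 5 PPAR-alpha targets seen first were highest of the 6 libraries, among them Pdk4, which restrains glucose oxidation, at 63.9 against 4.52 to 15.8 FPKM. In pregnant library 3, 4 of these 5 and 13 of 16 further tested PPAR-alpha targets were lowest of the 6 libraries, against 21.1% of all tested genes. The clock genes ran in parallel. In non-pregnant library 3 Arntl, the activator of the circadian clock, stood at 18.3 FPKM against 1.84 to 8.47 FPKM elsewhere. Dbp, an output gene of the opposite phase, stood there at 18.5 against 42.2 to 91.2 FPKM. All 5 genes of the Arntl phase were highest and 8 of 9 tested genes of the Per and Dbp phase were lowest in non-pregnant library 3, and 7 of those 9 were highest in pregnant library 3. Of all tested genes 35.8% were highest and 28.5% lowest in non-pregnant library 3, and 16.9% were highest in pregnant library 3.

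The sorted cells held some hepatocyte transcripts at high and others at low level. In non-pregnant library 1, for example, Alb stood at 1973 FPKM and Ttr at 386 FPKM, while Apoa1 stood at 4.09 FPKM and Fgb at 1.18 FPKM. Ptprc, or CD45, a gene of leukocytes that macrophages also express, stood at 0.0229, 0.0307 and 0.0124 FPKM in non-pregnant and 0.410, 0.255 and 0.125 FPKM in pregnant libraries.

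Macrophage transcripts were higher in the pregnant libraries, and a sort for biliary cells would be meant to remove macrophages. Deeper sequencing would not raise these values as such, since FPKM is already scaled to depth. The pregnant libraries held 0.875 times as many fragments as the non-pregnant ones, which is therefore no test of that explanation. RNA of macrophages among the sorted cells stays open: of 25 further macrophage genes 24 had a higher mean in pregnancy, with ratios of the group means from 0.987 to 19.0 (median 5.69), and 17, or 68.0%, were higher in all 3 pregnant than in all 3 non-pregnant libraries, below the 80% set for that explanation and above the 50% set against it, and they cannot be told apart from expression by biliary cells on that count. The further genes did follow the order of pregnant libraries 1, 2 and 3 seen in the markers, in 24 of 25 (96.0%) against 20.4% of all tested genes. These shares are of unlike sets. Only 6 of the 25 reached the mean of 1 FPKM of the tested genes, and the others needed only 10 fragments over all libraries. The order goes with macrophage RNA in amounts that differ between those libraries. Pregnancy itself may have changed the number of macrophages carried along or their genes, which was not tested.

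Ahsg and Fetub fell and A1bg rose. Less hepatocyte RNA in the pregnant libraries is argued against as the whole cause, since the other hepatocyte markers had a median log2 change of -0.149 (SD 0.434) where Ahsg had -1.60, and their median lay 0.679 above the -0.83 of Fetub. Among those markers Apoh (-1.19), G6pc (-0.99) and Fgg (-0.60) fell with them adjusted over the list alone. More hepatocyte RNA is argued against for A1bg, since the median of the hepatocyte markers was -0.166 (SD 0.513). A change of these genes in biliary cells with pregnancy stays open as a hypothesis and was not tested. For Fetub and A1bg, a change in hepatocytes whose RNA is carried at a steady level stays open too. For Ahsg, carried hepatocyte RNA is argued against as the main source. Ahsg stood at 516, 502 and 664 FPKM in non-pregnant libraries 1 to 3, where the hepatocyte markers had medians of 6.18, 8.03 and 8.88 FPKM. Some of those markers, such as Alb, were high as well.

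Cholesterol biosynthesis genes were low in non-pregnant library 3. A GC bias of that library is argued against, since 102.7% of the list's median log2 difference from the other non-pregnant libraries was kept after the GC trend was removed. Another feeding state or time of day of that animal may account for it: of 16 tested PPAR-alpha targets not looked at before, 15 (93.8%) were highest in that library, against 35.8% of all tested genes, though these targets are regulated together and are not independent. The labels used here give neither feeding nor time of collection, so part of the shift of the cholesterol list between the groups stays open to the same explanation.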
